A study of Mus musculus with 9 samples.

How the data were processed

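Total RNA from mouse brain was sequenced as mRNA libraries, 3 in each of groups C, L and H, per the labels. The authors deposited 1 table of FPKM values per gene and library, with a gene length column, per the file headers. The submitters' processing notes name the genome build GRCm38, and the aligner and the counting program are not given in the sources used here. The table held 2996 genes with the lowest Ensembl gene numbers, 1 to 21270, of which 2994 are protein coding in GENCODE M21, and 1 line without content was skipped. All other genes were not analysed here. Every Ensembl identifier matched GENCODE M21. Gene coordinates in the table equalled those of GENCODE M21 on GRCm38 for 20 genes, although the gene spans were equal for 2950, so the coordinates printed here were taken from GENCODE M21 on GRCm38 by Ensembl identifier and not from the table.

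Each FPKM value multiplied by the gene's length was a whole multiple of the value of 1 read within a tolerance of 0.01 reads, for 100% of values in every library. This gave the reads per gene and the denominator of each library, 15371513 to 20431208 reads. It also gave the precision of low values, since 3 reads on a transcript of 1 kb correspond to 0.147 to 0.195 FPKM. Values were otherwise used as deposited, with no further scaling in the main test.

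The design, the gene lists and the rule for named genes were fixed before the data were examined, and the design foresaw a count model. As the table held FPKM, the test laid down for a normalized unit was used. Values were transformed to log2(FPKM + 1), which understates changes of low genes, and genes over 1 FPKM in at least 3 libraries were tested (2226 genes). A linear model with the 3 groups was fitted to all 9 libraries in limma 3.58.1 under R 4.3.3 with a mean-variance trend and robust empirical Bayes moderation, leaving 6 residual degrees of freedom per gene before moderation. Contrasts were H against C, L against C and H against L, with an F test over the groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. With 3 libraries against 3 an exact permutation test cannot go below 0.1. Of 60 gene lists, 33 had at least 5 tested members, and these were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

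Named genes followed a rule. As no gene passed the threshold, the 5 smallest p-values in each direction were named, with a set of genes named whatever their values and the members of called lists with the smallest p-values. Of the set always named, Ttr, Hba-a1, Hbb-bs, Mbp, Cldn5 and Cdkn1a were not analysed here. Some genes that the rule names are not reported here. The fit and the list test were tested on simulated data before use. Counts were drawn at a dispersion of 0.02 around the real means and depths, with 200 of 2226 genes changed at mixed folds. Of genes changed 1.5-, 2- and 4-fold in H against C, 63.6%, 99.0% and 100% were recovered. With the real deviations shuffled over libraries the mean number of false calls was 9.65 per draw. For the list test, counts were drawn independently for each gene at the dispersion of 0.02. There a list of 20 genes raised 1.5-fold was called in 10 of 10 draws. Members were uncorrelated in these draws, so they do not show how camera performs on correlated members.

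Alternatives covered the pseudocount, the filter, quantile normalization, limma-voom with and without quality weights, the samples in the fit, the replicate number as a block, thresholds, the list test, and each library left out in turn. Added after the data were seen were scaling by median of ratios or upper quartile, limma without robust moderation, a covariate for regional marker content, the first residual component as a covariate, removal of each library's trend with gene length, and a fit without C1 and L3. Tables were read with pandas 2.3.3 under Python 3.11.15 and figures drawn with matplotlib 3.10.9.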

Results

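Gene expression was measured by mRNA sequencing in 9 libraries of perfused brain tissue from mice described as 24 months old. The exposed animals drank water containing perfluorooctane sulfonate (PFOS), a persistent fluorinated surfactant, for 7.5 months. Group L received 0.5 µg per litre and group H 50 µg per litre, and group C, for which the labels state no PFOS dose, served as the comparison group. Each group held 3 libraries. The values were deposited as FPKM, which scales the fragments of a gene by its transcript length and by the reads of the library. The library totals recovered from them were 17162748, 19263869 and 15371513 reads in C1 to C3, 16399627, 19999722 and 18348783 in L1 to L3, and 20431208, 18583511 and 18926364 in H1 to H3. The genes analysed here numbered 2996 and held 3008813 to 4153307 reads per library, and 2226 of them were expressed highly enough to test. All other genes were not analysed here, and every statement on a gene group covers its tested members alone. The labels do not say that each library came from a separate animal, so p-values then measure only the spread between these samples, which may be technical. Differences are given on the scale of log2(FPKM + 1), which understates the change of low genes.

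Brain region markers differed widely between libraries, also within exposure groups. The cerebellar granule cell gene Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072, GRCm38) stood at 253.7 FPKM in C1, 55.0 in L3, 14.8 in L1 and 2.48 in H1, and at 0.0603 or less in the other 5 libraries. The Purkinje cell gene Ppp1r17 followed the same order, with 202.6 FPKM in C1, 45.7 in L3, 16.9 in L1 and 2.40 in H1. Stx1a, a synaptic membrane protein listed among the pallial markers, was at 1.11 FPKM in C1 and 3.35 in L3, against 27.2 to 108.5 elsewhere. The striatal gene Adora2a, an adenosine receptor, was at 10.96 to 26.5 FPKM in C2, C3, L1 and H2 and at 0.811 or less in the other 5 libraries. On the first principal component of the 2226 tested genes, which held 58.8% of the variance, C1 lay at -28.2 and L3 at -19.2, and the other 7 libraries lay between -2.40 and 11.1. These differences cross the exposure groups, since C1 belonged to C and L3 to L, but they were not balanced over them. A score of the mean log2 level of cerebellar minus pallial markers was -2.47 to -1.12 in the H libraries. It was 6.19 in C1, 4.29 in L3 and 1.02 in L1, and -2.31 to -1.93 in C2, C3 and L2. Regional content may thus shift the comparisons with H as well as widen the spread within groups. Its whole share in either was not measured, as the score, used below as a covariate, covers cerebellum against pallium alone.

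**Figure D1:**
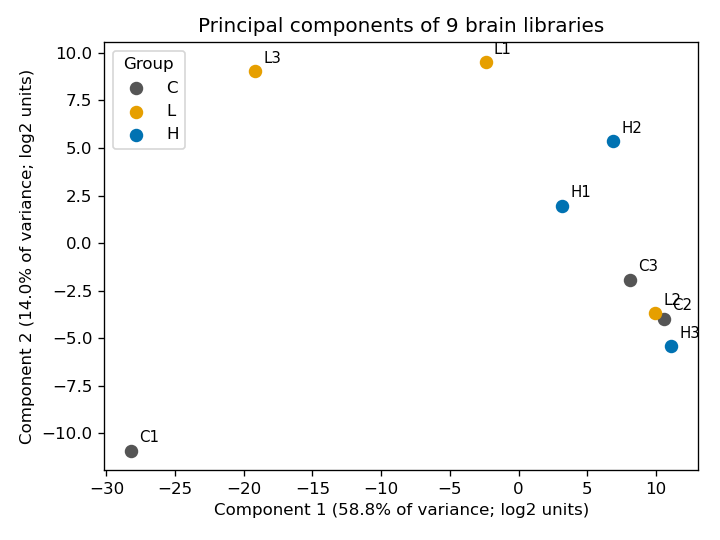
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1) over 2226 genes, coloured by group. C1 (-28.2) and L3 (-19.2) lie apart from the other 7 libraries on the first component, which holds 58.8% of the variance.

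**Figure D2:**
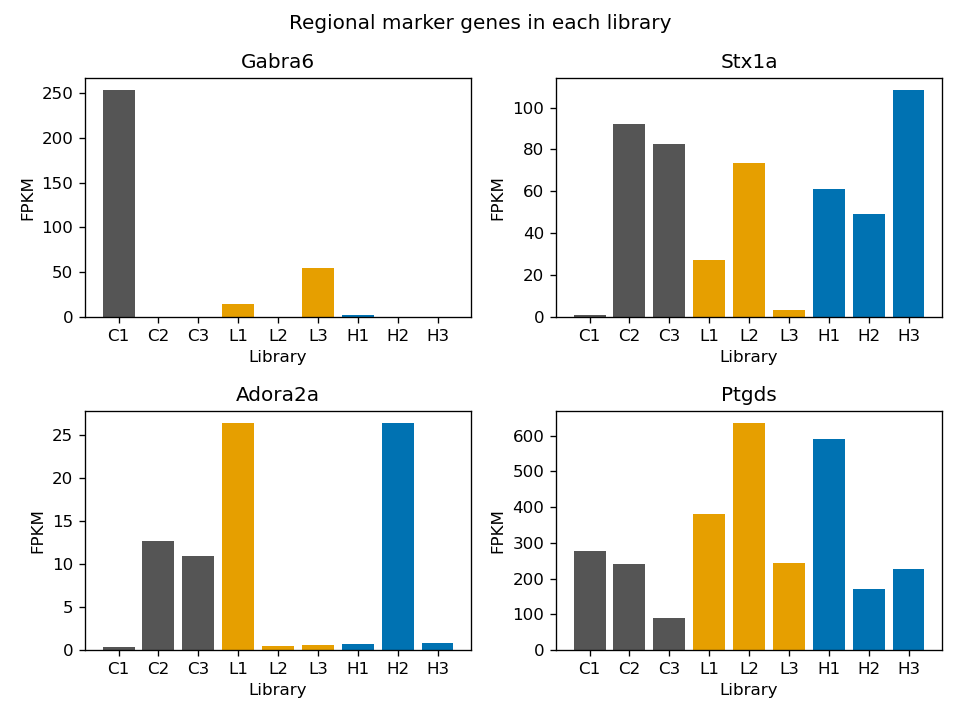
FPKM of 4 regional marker genes in each library, with bars coloured by group and linear axes that start at 0. Gabra6 is at 253.7 FPKM in C1 and 55.0 in L3, where Stx1a is at 1.11 and 3.35, Adora2a exceeds 10 FPKM in C2, C3, L1 and H2 alone, and the meningeal gene Ptgds is at 635.8 FPKM in L2 and 589.2 in H1.

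The comparison of H with C asked which transcripts differed in brains exposed to the higher PFOS concentration. Genes of protein synthesis, mitochondrial respiration and protein breakdown lay higher in H. All 13 tested cytosolic ribosomal protein genes had higher means in H, by 0.46 log2 units on average, as did 19 of 20 nuclear-encoded respiratory chain genes (0.34) and 12 of 13 proteasome genes (0.27). Examples were Rpl19 at 41.5 ± 6.07 against 29.6 ± 8.64 FPKM (SD, n = 3), Cox7c, a subunit of cytochrome c oxidase, at 109.0 ± 8.88 against 78.6 ± 23.1, and Psmd4, a ubiquitin receptor of the proteasome, at 40.6 ± 3.03 against 30.9 ± 5.42. Of 8 tested glucocorticoid responsive genes 7 lay higher, by 0.46 on average, among them Ddit4, a stress-induced inhibitor of mTORC1 signalling (24.0 ± 4.67 against 14.5 ± 5.25 FPKM), and Nfkbia, the inhibitor of NF-kappaB (17.4 ± 4.18 against 10.7 ± 3.92). All 6 tested cerebellar genes lay lower in H, by -1.40 on average, and C1 held the highest level of each. Outside these lists, mean pallial marker levels were 0.70, 0.31 and 1.19 in H1 to H3 against -2.37, 1.04 and 0.85 in C1 to C3. Pan-neuronal genes lay higher in H by 0.31 on average. Both had their lowest level in C1, and their groups overlapped.

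These 5 lists passed the camera test of limma at its preset correlation of 0.01, with adjusted p over 33 lists of 3.26e-05 for ribosomal proteins, 3.11e-05 for the respiratory chain, 0.000147 for the proteasome, 0.00133 for glucocorticoid responsive genes and 0.0499 for the cerebellum. With the correlation between members estimated from the data, none of the 33 passed (lowest adjusted p = 0.708 with an estimated correlation), and fry, which tests whether members move one way, called none (lowest adjusted p = 0.755). No member passed when adjusted over the list alone. The mean level of glucocorticoid responsive genes separated the H from the C libraries, and those of the other 4 lists did not. Mean ribosomal levels were -0.50, 0.30 and -0.54 in C1 to C3 against 0.45, 0.29 and -0.09 in H1 to H3, so that C2 lay above 2 of the H libraries. Log2 fold changes also fell with transcript length across genes, which are not independent replicates (Spearman rho = -0.26), and ribosomal and respiratory chain transcripts are short. With the length trend of each library removed, the ribosomal difference was 0.35, that of the respiratory chain 0.22 and that of the proteasome 0.22. The cerebellar difference was -0.09 with the marker score of regional content as a covariate. That score is built from the same cerebellar genes, so this shrinkage was fixed in advance and is no evidence. The cerebellar call was also lost without H2 (camera, adjusted p = 0.0974) and without H3 (0.0986). Its adjusted p from camera or fry ranged from 1.73e-06 to 0.856 over all alternatives. Without C1, L1 or L3 fewer than 5 cerebellar genes were left to test, while the other 4 lists kept their call without any single library. Their size still depended on single libraries, as the respiratory chain difference was 0.54 without C2 and 0.20 without C3, the ribosomal 0.74 without C2, and the cerebellar -2.24 without C2 and -2.25 without C3.

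Among single genes, the smallest p-values belonged to Pfdn2 and Mafk. Pfdn2, a subunit of the prefoldin chaperone (ENSMUSG00000006412, chromosome 1, 171345670 to 171359254, GRCm38), was at 49.2 ± 1.24 FPKM in H and 32.1 ± 5.40 in C (SD, n = 3), a log2 difference of 0.61 ± 0.14 (SE). Mafk, a small Maf transcription factor (ENSMUSG00000018143, chromosome 5, 139791513 to 139802653), was at 3.89 ± 0.233 against 2.44 ± 0.347 FPKM, a difference of 0.51 ± 0.12. Next among the higher genes came the mitochondrial ribosomal protein gene Mrpl22 (0.54), the mitochondrial oxoglutarate carrier Slc25a11 (0.45) and Fsd1 (0.42). Lower in H were the kinase gene Akt2 of insulin signalling (ENSMUSG00000004056, chromosome 7, 27591552 to 27640826) at 10.3 ± 1.28 against 14.9 ± 2.03 FPKM, a difference of -0.49 ± 0.14, and Ylpm1 (-0.52), the oxysterol-binding protein gene Osbp2 (-0.45), Gga3 (-0.36) and the IGF1 receptor gene Igf1r (-0.41). In all 10 genes the H and C libraries did not overlap, but none passed the threshold (limma, adjusted p = 0.89 for each). Angptl4, a secreted inhibitor of lipoprotein lipase and a target of PPAR transcription factors (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), was at 1.67 ± 0.490 against 0.710 ± 0.0911 FPKM (log2 difference 0.63 ± 0.27), and the lipid droplet gene Plin4 at 9.42 ± 2.63 against 6.20 ± 0.473, both without overlap and neither past the threshold. Of the 8 tested PPAR alpha target and fatty acid oxidation genes, 6 lay higher, by 0.18 on average, and the list was not called (camera, adjusted p = 0.358). The astrocyte filament gene Gfap (-0.18 ± 0.41), Fos (-0.43 ± 0.34) and Pdk4 (0.26 ± 0.22) had overlapping groups.

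No gene passed an adjusted p of 0.05 in H against C (limma, lowest adjusted p = 0.89), and limma-voom on the recovered reads called 0 as well, with 68 genes at an unadjusted p under 0.05, or 111 with quality weights. In limma, at an unadjusted p under 0.05 there were 71 genes, 41 higher and 30 lower, where chance alone gives 111.3. That number was 38 without C1, 274 without C2, 18 without H1 and 19 without H2. It was 319 with the first residual principal component as a covariate. This component is taken from the spread within groups, so it leaves log2 differences as they were and can lower p-values by construction. In 229 genes (10.3%) the groups did not overlap, where chance gives 10%. The median 95% confidence interval of a log2 difference reached 0.45 to either side, or 1.36-fold. In data simulated at the observed spread, 200 of 2226 genes were changed at once, each by 1.5-, 2- or 4-fold on the scale of FPKM + 1. In this comparison 24.6% of those changed 1.5-fold, 61.3% of those changed 2-fold and 92.0% of those changed 4-fold were recovered. The adjusted threshold depends on how many genes change, so these shares do not apply where only a few genes change. They also overstate the recovery of equal folds of expression in low genes, where a fold of FPKM + 1 is a larger fold of FPKM.

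**Figure D3:**
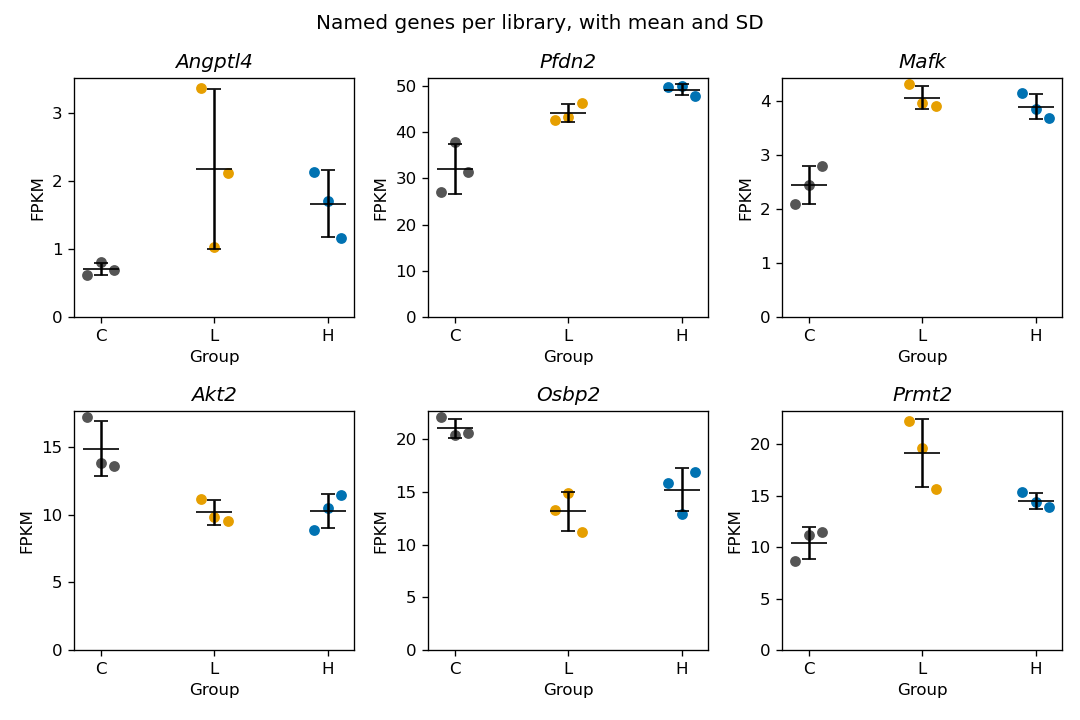
FPKM of 6 genes in each library by group, with the mean and SD of 3 libraries, on linear axes that start at 0. Every L and H library lies above every C library for Angptl4, Pfdn2, Mafk and Prmt2 and below for Akt2 and Osbp2, with no gene past an adjusted p of 0.05.

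The comparison of L with C asked the same of the lower concentration. Lists of reactive astrocyte, disease-associated microglial and meningeal genes lay higher in L, while oligodendrocyte and myelin genes differed by -0.09 on average. That mean covers opposite shifts, with oligodendrocyte levels of -0.07, -0.75 and 0.71 in L1 to L3 against 0.21, 0.01 and -0.07 in C1 to C3. All 8 tested reactive astrocyte genes, of 9 measured, had higher means in L, by 0.55 log2 units on average, led by the extracellular matrix gene Fbln5 at 3.58 ± 1.25 against 1.16 ± 0.485 FPKM (SD, n = 3) and the small heat shock gene Hspb1 at 6.13 ± 3.16 against 2.45 ± 0.526. All 6 meningeal and fibroblast genes lay higher (0.67 on average), among them the collagen gene Col1a1 (0.43) and Vtn (0.49), as did all 9 tested genes, of 13 measured, of disease-associated microglia (0.28), among them the lipid carrier Apoe (0.41) and the chemokine Ccl6 (0.42), all 13 proteasome genes (0.21; Psma6, 0.31) and all 13 ribosomal protein genes (0.28; Rps15a, 0.24). Of 10 tested insulin and IGF signalling genes 8 lay lower (-0.20), with Akt2 at -0.50 and Igf1r at -0.34, and of 11 calcium signalling genes 9 lay lower (-0.21), with the calcium channel subunit gene Cacnb4 at -0.81 and Cacna1d at -0.25. Ordinary markers of the same cell types also had higher means in L: all 4 tested genes of homeostatic microglia, by 0.48 on average, too few for the list test, and 5 of 7 general astrocyte genes, by 0.16. Regional markers differed as well, with overlapping groups. Mean hypothalamic levels were 1.96, -0.60 and 0.67 in L1 to L3 against -0.09, -0.85 and -0.58 in C1 to C3. Mean pallial levels were -0.26, 0.87 and -2.33 against -2.37, 1.04 and 0.85.

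Camera called these 7 lists at its preset correlation, with adjusted p of 0.00268 for reactive astrocytes, 0.00603 for the proteasome, 0.0157 for the meninges and for insulin and IGF signalling, 0.0184 for microglia and 0.0276 for ribosomal proteins and calcium signalling. None of the 33 lists passed with an estimated correlation (lowest adjusted p = 0.457 with an estimated correlation) or with fry (lowest adjusted p = 0.331). Adjusted over the list alone, 2 reactive astrocyte genes passed, Fbln5 and Hspb1, and 0 in the other 6 lists. These lists were picked from the same values, so that adjustment does not control error over all lists. Over all tested genes both had an adjusted p of 0.998 (limma). The calls depended on single libraries, with 2 lists called without C3, 3 without C2 and 4 without L3. The reactive astrocyte call was lost without C2 (adjusted p = 0.128) and without L3 (0.0676), with a range of 0.000175 to 0.457 over all alternatives. The meningeal call was lost without C2 (0.0926), C3 (0.231) or L2 (0.167), the microglial call without C1 (0.393), C2 (0.122), L1 (0.118) or L3 (0.517), and the proteasome call without C1 (0.321), C3 (0.101) or L2 (0.0687). The ribosomal call was lost without C1 (0.757), C3 (0.268) or L2 (0.613), the insulin and IGF call without C2 (0.0596), C3 (0.231) or L3 (0.0704), and the calcium call without C2 (0.172), C3 (0.268) or L3 (0.658). Without L3 the calcium difference was 0.0026, and without L1 -0.32. The ribosomal difference was 0.15 without C1, 0.55 without C2, 0.13 without C3, 0.09 without L2 and 0.45 without L3, the microglial 0.44 without L2, the meningeal 1.01 without C1 and 0.36 without C3, the proteasome 0.32 without C2, and the insulin and IGF -0.13 without L3. L3 was the library with the highest reactive astrocyte level (0.83, against 0.26 in L1 and 0.05 in L2), and L2 the one with the highest meningeal level (0.93, against 0.21 and 0.20). Without both C1 and L3, 4 lists were called, and 1 with the length trend removed.

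The gene with the smallest p-value was Prmt2, an arginine methyltransferase (ENSMUSG00000020230, chromosome 10, 76207222 to 76237865, GRCm38), at 19.2 ± 3.32 FPKM in L and 10.4 ± 1.57 in C (SD, n = 3), a log2 difference of 0.82 ± 0.16 (SE). Mafk (0.56 ± 0.12), the smooth muscle myosin gene Myh11 (0.77 ± 0.17), the laminin receptor gene Bcam (0.58 ± 0.16) and Pcbd1, which recycles the cofactor tetrahydrobiopterin (1.69 ± 0.46), followed. Lower in L were Osbp2 (ENSMUSG00000020435, chromosome 11, 3703731 to 3863903) at 13.2 ± 1.86 against 21.1 ± 0.912 FPKM, a difference of -0.65 ± 0.14, Akt2 (-0.50 ± 0.14), the neuronal splicing regulator Rbfox1 (-0.48 ± 0.14), Cacnb4 (-0.81 ± 0.26) and Numb (-0.46 ± 0.15). Groups did not overlap in any of these 10 genes, and none passed the threshold (limma, adjusted p of 0.962 to 0.998). Angptl4 was at 2.18 ± 1.17 against 0.710 ± 0.0911 FPKM (0.83 ± 0.27, without overlap), while Gfap (0.35 ± 0.41), Fos (-0.38 ± 0.34), Pdk4 (0.22 ± 0.22) and Plin4 (-0.28 ± 0.28) had overlapping groups.

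No gene passed an adjusted p of 0.05 in L against C (limma, lowest adjusted p = 0.962). The count was also 0 with limma-voom, which had 77 genes at an unadjusted p under 0.05, or 109 with quality weights. In limma there were 87 genes at an unadjusted p under 0.05, 62 higher and 25 lower, against 111.3 by chance. The 87 became 142 without C1, 134 without C2, 45 without L1 and 160 without L2. It was 201 with the regional marker score as a covariate and 186 with the first residual principal component. There were 148 genes (6.65%) without overlap against 10% by chance.

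**Figure D4:**
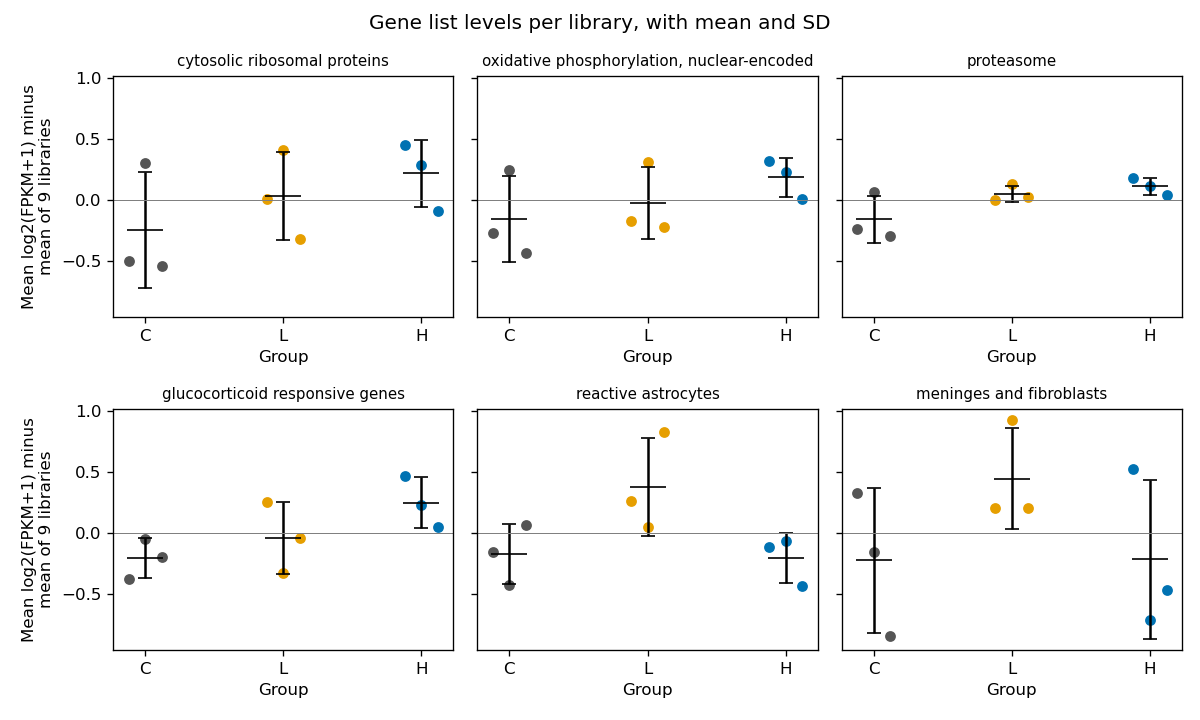
Mean level of 6 gene lists in each library by group, as mean log2(FPKM + 1) minus the mean of the 9 libraries, with the mean and SD of 3 libraries. Ribosomal, respiratory chain and proteasome levels are low in C1 and C3 and higher in C2, the glucocorticoid responsive levels of H lie above those of C, and the highest reactive astrocyte level belongs to L3 and the highest meningeal level to L2.

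The comparison of H with L asked whether the concentrations differed from each other. Reactive astrocyte genes lay lower in H for all 8 tested members, by -0.59 on average, with the proteoglycan gene Srgn at 3.40 ± 0.474 against 6.26 ± 2.32 FPKM (SD, n = 3) and Fbln5 at 1.58 ± 0.742 against 3.58 ± 1.25. All 6 meningeal genes (-0.66; Col1a1, -0.46, and Dcn, -1.28), all 9 tested genes of disease-associated microglia (-0.23; Csf1, -0.30, and Cd68, -0.54) and 7 of 8 genes of the unfolded protein response (-0.18; Xbp1, -0.29, and Calr, -0.26) also lay lower. Higher in H were 18 of 20 respiratory chain genes (0.21; Cox7c, 0.45, and Ndufs3, 0.38), 7 of 8 glucocorticoid responsive genes (0.29; Plin4, 0.79, and Ddit4, 0.47), 9 of 11 calcium signalling genes (0.22; Cacnb4, 0.56, and Atp2b1, 0.77) and 12 of 13 ribosomal protein genes (0.18; Rps18, 0.38, and Rpl19, 0.25). Ordinary cell type and regional markers also differed: means were lower in H for 6 of 7 general astrocyte genes (-0.28), 3 of 4 homeostatic microglia genes (-0.22) and all 6 cerebellar genes (-1.53; camera, adjusted p = 0.0506), and higher for all 4 pallial genes (1.30).

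Camera called these 8 lists, with adjusted p from 3.54e-05 for reactive astrocytes to 0.0308 for ribosomal proteins and microglia, and none passed with an estimated correlation (lowest adjusted p = 0.565 with an estimated correlation) or with fry (lowest adjusted p = 0.189). No member passed when adjusted over the list alone. Without C1 and L3, 4 lists were called, and the ribosomal (0.01) and calcium (0.01) differences were near 0 without L3 alone. Leaving out C1 or H2 gave 5 lists. The reactive astrocyte call was kept without any single library, with a difference of -0.38 without L3. The respiratory chain difference was 0.14 without L1, 0.38 without L2 and 0.11 without L3, the ribosomal 0.37 without L2, 0.07 without H1 and 0.34 without H3, and the glucocorticoid 0.44 without L1, 0.14 without L2 and 0.18 without H1. The microglial difference was -0.15 without L1, -0.39 without L2, -0.37 without H2 and -0.15 without H3, and the meningeal -0.41 without L2, -1.03 without H1 and -0.42 without H2. The respiratory chain call was lost without L1 (adjusted p = 0.0697), the meningeal call without L2 (0.287) or H2 (0.0753), the glucocorticoid call without L2 (0.357) or H1 (0.0726), the unfolded protein response call without C1 (0.0550) or H2 (0.0599), and the calcium call without L3 (0.524) or H3 (0.155). The ribosomal call was lost without C1 (0.0624), L1 (0.0894), L3 (0.524), H1 (0.281) or H2 (0.108), and the microglial call without C1 (0.118), L1 (0.258), L3 (0.447), H1 (0.253) or H3 (0.155).

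Single genes ranked highest in H were Plin4 (9.42 ± 2.63 against 5.21 ± 2.28 FPKM; log2 difference 0.79 ± 0.28, SE), Pttg1 (0.32), Slc30a4 (0.59) and Atxn3 (0.35). Those lowest were Myh11 (3.90 ± 0.678 against 6.28 ± 0.174 FPKM; -0.58 ± 0.17), Dcakd (-0.53), the matrix gene Fbln1 (-0.67), Fxyd5 (-0.53) and Srgn (-0.68). Groups overlapped for Slc30a4 and did not for the other 8 of these genes. Gfap (-0.53 ± 0.41), Fos (-0.05 ± 0.34), Angptl4 (-0.20 ± 0.27) and Pdk4 (0.04 ± 0.22) overlapped. No gene passed an adjusted p of 0.05 in H against L (limma, lowest adjusted p = 0.961). The count was also 0 with limma-voom, which had 32 genes at an unadjusted p under 0.05, or 165 with quality weights. In limma 30 genes had an unadjusted p under 0.05, 3 higher and 27 lower, and that number was 93 without C1, 18 without L1, 184 without L2, 19 without L3, 19 without H2 and 7 without H3. It was 50 with the regional marker score as a covariate, 67 without both C1 and L3, and 220 with the first residual principal component. The groups did not overlap in 202 genes (9.07%), where chance gives 10%.

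Across all 3 groups, the F test of limma called 0 genes (lowest adjusted p = 0.958, with 47 genes at an unadjusted p under 0.05), and limma-voom also called 0, with 49 genes at an unadjusted p under 0.05. The F test had 113 such genes with the regional marker score as a covariate, 79 without both C1 and L3, and 285 with the first residual principal component. With 1 library left out the number ranged from 24 without H2 to 124 without C2, with 84 without C1 and 106 without L2. The log2 fold changes of L and of H against C correlated across the 2226 genes at r = 0.497. Unchanged groups compared with the same C libraries gave a mean of 0.503 in 100 simulations, with a range of 0.389 to 0.619, and the observed covariance of 0.0396 lay below the simulated 0.0566. With the 9 libraries shuffled over the groups, 52 of 100 shuffles gave a correlation as high, with a median of 0.508 and a range of -0.35 to 0.95. The correlation thus did not exceed that of unchanged groups sharing their C libraries, which were too few to be divided between the comparisons. The correlation was 0.133 without L2 and 0.761 without C2.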

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

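The tests of depth, regional content, exposure group, gene length and tissue share below, and the splits for gene counts, were chosen only after the results they examine were seen, while the splits for list counts were set before. H and L were compared directly, and camera at its preset correlation called 8 lists, with adjusted p-values of 3.54e-05 for reactive astrocytes, 0.00153 for the respiratory chain, 0.00346 for the meninges, 0.00507 for glucocorticoid responsive genes, 0.0179 for the unfolded protein response, 0.0191 for calcium signalling, and 0.0308 for both ribosomal proteins and disease-associated microglia. None held with an estimated correlation (lowest adjusted p = 0.565) or with fry (0.189), so a difference between the concentrations is not established. The 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 8 lists, 1 of 10 splits gave as many, and the highest other split gave 6. Groups of 3 libraries were not tested for outlying samples.

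The libraries C1 and L3 stood apart on the first principal component. Sequencing depth is argued against, since C1 (17162748 reads) and L3 (18348783) lay within the 15371513 to 20431208 reads of the other 7 libraries. The gap to those libraries was 16.8 both before and after thinning every library to 3008813 reads. The depths differed too little for thinning to move the gap much, so this adds little. Exposure group alone is argued against by membership, since C1 and L3 belong to different groups and each lay apart from the other libraries of its own group; the C range of 3.54 times the largest difference between group means restates this and adds no evidence. Different brain regions in the tissue taken are a candidate explanation: on a score of cerebellar minus pallial markers, led by Gabra6 at 253.7 FPKM in C1 and 55.0 in L3, C1 and L3 exceeded all other libraries by at least 3.27 log2 units. Whether dissection, pooling or sample handling produced this was not tested.

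Ribosomal protein, respiratory chain and proteasome lists were higher in H than in C. A length trend over all genes is argued against as the whole cause, since at least 64.6% of each difference was left with it removed. So is the share of cerebellar against pallial tissue, with at least 70.3% left under the marker score. Both corrections left camera's calls at its preset correlation and shrank the differences, and the uncorrected calls were lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation for each list) and with fry (0.755). The length correction cannot exclude a library bias that follows length in another way. Deviations of a library from the mean correlated with gene length (Spearman rho) at 0.201, -0.141 and 0.253 in C1 to C3. In H1 to H3 the values were -0.216, -0.183 and -0.012. C1 and C3, with the positive values, also had the lowest levels of these lists among these libraries. Such a bias, content of other regions, RNA quality and PFOS exposure stay open and were not tested apart. For the number of lists in H against C the 10 splits are too few for a share under 0.05, with 5 lists in the real split, 2 of 10 splits giving as many and 6 in the highest other.

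The mean level of glucocorticoid responsive genes was higher in each of the 3 H libraries than in any C library, although 1 of its 8 members was lower in H and Ddit4 and Nfkbia each overlapped between the groups. A length trend over all genes and the share of cerebellar against pallial tissue are argued against as the whole cause. With these corrections 98.2% and 97.8% of the difference were left. An effect of PFOS on this list may be proposed only as a hypothesis, and handling or time of day at sampling was not tested. The list was picked out after its values were seen, and such separation was common by chance: of 33 lists, 3 separated H from C, 4 L from C and 4 H from L, where chance gives 3.3 each. Its exact permutation p was 0.1, the smallest that 3 against 3 allows, and 0.724 adjusted over 99 tests.

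For gene counts the real value of 0 was met by all 10 splits in H against C, L against C and H against L, which says nothing on chance because no count can be lower. The highest other split gave 0, 109 and 0 genes in these comparisons. The split with 109 genes set C1, L1 and L3 against C2, C3 and L2, which points to a structure of the samples other than exposure, as C1, L3 and L1 hold the most Gabra6. Across the 3 groups, 100 of 100 splits likewise met the real count of 0, with 31 genes in the highest other, which again says nothing on chance. For the lists of L against C the splits are likewise too few, with 7 lists in the real split, 2 of 10 splits giving as many, and 7 in the highest other.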

How the results depend on the processing

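The covariates, scaling by median of ratios or upper quartile, limma without robust moderation, length correction and the fit without C1 and L3 were chosen after the data were seen. The planned count-model tests and a surrogate variable were not run, and the scalings named above and the residual component took the place of planned counterparts. The count of changed genes was 0 in every comparison under every setting run, except 3 in H against L with the first residual component as a covariate (Stx1a, Vsig2 and Fhl2, all low in C1 and L3). That component is taken from the residuals of the same fit. It leaves every log2 difference as it was and lowers the residual spread of the genes that follow it. These 3 calls, and the higher counts at an unadjusted p under 0.05 with this covariate, are therefore no evidence of a difference. Of 2075 values for named genes under alternatives, 2061 kept their direction and side of the threshold and 14 reversed. Of 376 for lists, 258 did so, 117 lost the call and 1 reversed. Many of the gene values could not change, since settings such as another threshold or a library left out of the third group leave the estimate as it is. The lowest adjusted p of any gene in the main test was 0.89 (limma), so the side of the threshold could hardly change either. The gene tally is therefore no measure of stability. With an estimated correlation or fry, 0 lists were called in each comparison. The estimated setting kept the fit and the list differences and changed only how camera treats correlation between members, so its lost calls come from that. The p-values at the preset correlation thus rest on the assumed 0.01 and are too small if members are more correlated. For fry the cause was not tested. In L against C, 4 lists were called with the marker score, 4 without C1 and L3, 1 with the length trend removed, 3 at a preset correlation of 0.05, and 2 to 9 with a library left out. In H against L these were 4 with the marker score, 4 without C1 and L3, 5 at 0.05, and 5 to 9 with a library left out. The correlation of fold changes was 0.68 without C1 and L3 and 0.13 to 0.76 with a library left out. Gfap in L against C was -0.0094 with quality weights, -0.14 without C1 and L3 and -0.0527 to 0.61 with a library left out. Pdk4 in L against C was -4e-04 without C1 and L3, and Fos in H against L 0.0226 after quantile normalization. With a library left out, Gfap in H against C ranged from -0.38 to 0.13, Plin4 in L against C from -0.54 to 0.0178, Fos in H against L from -0.41 to 0.15, Angptl4 in H against L from -0.49 to 0.0671, Pdk4 in H against L from -0.13 to 0.22, and the calcium list in L against C from -0.32 to 0.0026. The cause of these reversals was not tested. Replicate numbers did not pair the libraries: 3 of 9 same-number pairs correlated above 0.1, with a range of -0.51 to 0.68, and 3 libraries correlated best with their own number. With the replicate number as a block, 0 genes were called in each comparison and 5, 7 and 9 lists in H against C, L against C and H against L. Depth limits low genes most, as 3 reads on 1 kb equal 0.147 to 0.195 FPKM.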

Other observations

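Further regional genes varied between libraries. Ahi1, listed with hypothalamic genes, was at 34.7 to 96.6 FPKM in L, above the 21.3 to 29.0 of C, and at 25.6 to 50.7 in H. The genes that follow overlapped between the exposure groups. Trh, the thyrotropin-releasing hormone precursor of the hypothalamus, was at 29.1 FPKM in L1 and at 0.987 to 5.32 in the other 8 libraries, and Nts, a neuropeptide precursor, was at 26.7 in L1 and 15.8 in H2 against 5.29 or less elsewhere. The glycine receptor gene Glra1, typical of brainstem and spinal cord, reached 35.2 FPKM in L3 and 4.66 or less elsewhere. The meningeal gene Ptgds was at 635.8 FPKM in L2 and 589.2 in H1, and at 89.4 in C3. Calb2, listed with several regions and cell types, ranged from 4.47 FPKM in C2 to 229.3 in C1, with 112.3 in L3. The interneuron genes Vip and Sst went the other way. They were lowest in C1 (0.308 and 15.6 FPKM) and next lowest in L3 (2.18 and 62.4).

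Of 2226 tested genes, 51 had all 6 exposed libraries on the same side of all 3 C libraries, 38 above and 13 below, where chance gives 53.0. Those with the largest differences above C in H were Pcbd1 (1.07 in H and 1.69 in L), Pnck (0.68 and 0.83) and Angptl4 (0.63 and 0.83), and below C Akt2 (-0.49 and -0.50), Osbp2 (-0.45 and -0.65) and Numb (-0.42 and -0.46). A single gene had every L library on one side of C and every H library on the other.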
